A study of Drosophila melanogaster with 2 samples.

How the data were processed

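Chromatin from whole Drosophila melanogaster embryos of 0 to 18 h carrying a sisA-eGFP transgene was sonicated to fragments of 200 to 800 bp, per the labels, and precipitated with an anti-GFP antibody. The labels call the 2 samples biological replicates of 1 group. They do not say whether the embryos came from separate cages, and the sex of the embryos is not stated. The antibody field names sisA, which was read as the tagged target. The labels name a possible control experiment. Control libraries and reads were not used here, so background could not be measured in the same way.

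The deposited data were peak lists in narrowPeak format on dm6, per the file listings. The peak caller and its version, the aligner, and the treatment of duplicate and multiply matching reads are not given in the sources used here. Per the file listings, the conservative list of 5202 peaks and the longer list of 5643 peaks were derived by the authors from the alignments of both replicates, and a list of 4751 peaks for replicate 1 and of 3485 for replicate 2 from each replicate alone. Each came with a longer ranked list of 101511 to 120515 peaks before thresholding. The signal of each peak is the authors' peak caller's value, deposited without a stated normalization. It was tested within a list, and between the lists of the replicates only by rank correlation, although 1 figure plots the values of both lists on axes with a line at equal signal. The score of each peak, deposited by the authors, is a whole number derived from the irreproducible discovery rate (IDR), and every thresholded peak had a score of at least 830, which is the score of an IDR of 0.01. All 5202 conservative peaks were found in the first ranked list, and 217 ranked peaks at or past that score were not in the conservative list. Depth per replicate is unknown, so no interval that needs read counts is given. Intervals on odds ratios cover the sampling of genes only.

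Coordinates were written 1-based. Genes and TSSs came from Ensembl release 115 (annotation BDGP 6.54) and sequence from the same assembly as dm6, after chromosome names and lengths were compared. Tests used the arms 2L, 2R, 3L, 3R, 4 and X, which left out 69 peaks of the conservative list. The gene symbols h, frs and nos were matched to hry, Z600 and nanos in the annotation, and no list member was missing from it. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 merged and intersected intervals.

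The conservative list was the main list throughout. Summits of the replicates were matched within 100 bp and set against 1000 circular shifts of a list along each arm. Location was assigned in the order promoter (500 bp to each side of a protein-coding TSS), 5' UTR, coding sequence, intron, 3' UTR and intergenic, and set against 1000 shifts, two-sided. Introns were gene bases outside every exon, so that a 3' UTR base counted as 3' UTR. A gene was occupied when a summit lay within 1000 bp of any of its TSSs. Occupied genes were compared between X and autosomal arms, and between each of 22 gene lists and all other protein-coding genes (for tRNA and snoRNA lists, all other genes), by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Odds ratio intervals are at 95%. Median signals of promoter and other peaks were compared by a permutation test with 100000 resamples.

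Each of 18 consensus motifs, searched on both strands, was counted in windows of 100 bp to each side of the summit. The share was compared with the mean of the windows centred 500 bp to each side, and tested against the right-hand window by an exact McNemar (binomial) test with Benjamini-Hochberg adjustment. All 2080 words of 6 bases, with reverse complements merged, were tested in the same way.

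The main list, tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The rule named the genes nearest to the 20 strongest peaks, every member of the sex determination list, and for every other list the 4 members with the strongest peak within 1000 bp of a TSS. PlexA and CG4615 were named after their values were seen. The lists covered X signal and sex determination, dosage compensation, gap and pair-rule, segment polarity and Hox, dorsal-ventral, cellularisation, endoderm, mesoderm, neural, E(spl), bZIP, ribosomal protein, proteasome, histone, tRNA, snoRNA, chemosensory receptor, chorion and yolk, heat shock, hemocyte and fat body, cuticle and germ cell genes.

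Alternatives were the longer list, the peaks with a signal above the list's median (called the stronger peaks), each replicate's own list, promoters of 250 or 1000 bp, TSS distances of 500 or 2000 bp, gene bodies with 2000 bp upstream, a single TSS per gene, other motif windows, the left-hand flank for words, and a background of 10423 promoters of genes without a summit within 2000 bp. Other matching rules were tried for replicate agreement. Words of 8 bases, removal of peaks with a signal under 20, a rotation of gene lists along the gene order and 1-Mb blocks were added after seeing the data.

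The tests were tested on simulated data with 5133 peaks. On random peaks 1 of 22 gene lists, 0 of 18 motifs and 0 of 2080 words were called, and 2 of 2 planted lists and 1 of 1 planted motif were recovered. Over 20 further random sets, drawn after that result, 2 list calls were made in all. The X odds ratio on random peaks had a median of 1.08, and that of snoRNA genes 0.863.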

Results

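Sites bound by a sisA-eGFP fusion protein were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with an anti-GFP antibody in whole Drosophila melanogaster embryos aged 0 to 18 h. The sisA gene lies on the X chromosome and encodes a basic leucine zipper (bZIP) protein, one of the X-linked signal elements whose dose switches on the master sex determination gene Sxl in female embryos. There were 2 biological replicates of 1 group, so the comparisons below are between replicates, between parts of the genome and between groups of genes. The data were lists of peaks on the dm6 genome. The number of reads behind each peak, and so the depth of each replicate, is unknown. The height of a peak is the authors' own signal value, which was used to rank, describe and test peaks within a list and, by rank correlation, to compare the lists of the replicates.

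The first comparison asked which sites were found reproducibly. The conservative list of peaks kept from both replicates held 5202 peaks, of which 5133 lay on the arms 2L, 2R, 3L, 3R, 4 and X. These covered 1522 kb, or 1.14% of the arms, with a median width of 340 bp and a median signal of 128 (interquartile range 86.3 to 220). The strongest peak had a signal of 3554 and lay 35 bp upstream of a transcription start site (TSS) of Ugalt, which encodes a UDP-galactose transporter, at X from 2703696 to 2704070 (summit 2703887; 1912 in replicate 1 and 1660 in replicate 2). The reference sequence around that summit, at X from 2703867 to 2703907, was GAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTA. Next in rank came CG14100 with a signal of 3268, Adf1, a transcription factor gene with its peak in an intron (2657), CG7601 (2642), CG11050 (2577) and the Polycomb group gene ph-p (2534). The nearest TSS of the others among the strongest 20, in falling order of signal, was that of Tcs5, mRpL41, Chro, HmgZ, Shc, CG5611, px, CG13323, CenG1A, PNPase, Art3, mRpL23, lncRNA:CR45643 and Sox14, with signals from 2528 down to 1779. The summit assigned to CG13323 lay between genes, 11911 bp from that TSS. Among them mRpL41 and mRpL23 encode proteins of the mitochondrial ribosome, Chro encodes the chromatin protein Chromator, and Sox14 encodes a transcription factor. Of these 20 summits 14 lay in promoters, 4 in introns and 2 between genes, and 15 were upstream of the nearest TSS. Each of the 20 had a matching summit in the ranked lists of both replicates.

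Replicate 1 alone gave 4720 peaks on the arms and replicate 2 gave 3408. A summit of replicate 1 lay within 100 bp of 86.4% of the summits of replicate 2 (2946 of 3408), and 62.4% of the summits of replicate 1 were matched in replicate 2. Shifting 1 list around each arm gave mean matches of 0.711% and 0.519%, and no shift passed 1.20% or 0.890% (circular-shift permutation test, one-sided, p = 0.001 for both, the smallest they can give). Over the 2946 matched pairs the median distance between summits was 16 bp, and the signals of the replicates had a Spearman rho of 0.889 across peaks, which are not independent replicates. In the unthresholded ranked list of the other replicate, 90.4% of replicate 1's peaks and 95.7% of replicate 2's had a match, against 15.8% and 15.1% after shifting.

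**Figure D1:**
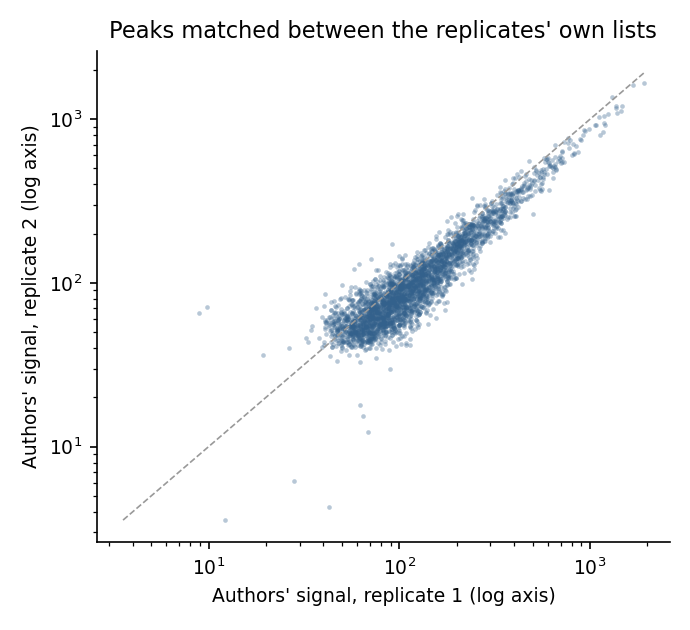
Signal of matched peaks in replicate 1 and replicate 2, on logarithmic axes, for the 2946 pairs of summits within 100 bp of each other, with a dashed line at equal signal. The normalization of the signals is not given in the sources used here, so the line is a guide only. The Spearman rho across peaks was 0.889.

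The second comparison asked where summits lay relative to genes. Promoters, taken as 500 bp to each side of a protein-coding TSS, held 1905 summits (37.1%), against a mean of 11.5% after circular shifts (SD 0.592), a ratio of 3.23. Coding sequence held 145 summits (2.82% against 13.9%) and 3' UTRs held 42 (0.818% against 4.55%), at ratios of 0.203 and 0.180. The coding sequence ratio was lower in the lists of replicate 2 alone (0.101) and replicate 1 alone (0.0502) and among the stronger peaks (0.00842), and there it lay below that of 3' UTRs (0.161, 0.158 and 0.128). Intergenic sequence held 1026 (19.99% against 29.9%) and 5' UTRs 23 (0.448% against 0.793%). Introns held the most summits, 1992 or 38.8%, close to their shifted mean of 39.3%. Promoters instead held more than introns in replicate 2 alone (41.5% against 37.1%) and replicate 1 alone (39.5% against 39.3%). The same was seen among the stronger peaks (45.3% against 36.8%) and with promoters of 1000 bp to each side (46.5% against 32.4%). The circular-shift permutation test over 1000 shifts, two-sided, gave p = 0.002 for promoters, coding sequence, 3' UTRs and intergenic sequence, the smallest they can give, p = 0.00799 for 5' UTRs and p = 0.647 for introns. With promoters of 1000 bp to each side, introns fell below their shifted mean as well, at a ratio of 0.891 (permutation p = 0.002), and among the stronger peaks the 5' UTR ratio of 0.586 no longer passed the threshold (permutation p = 0.0799).

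Promoter summits sat upstream of the TSS in 83.7% of cases (1595 of 1905), at a median signed distance of -111 bp (interquartile range -196 to -48). Away from promoters, 2747 summits (53.5%) were more than 1000 bp from every protein-coding TSS. Promoter peaks had a median signal of 157 (interquartile range 99.2 to 285, n = 1905) and all other peaks 114.8 (81.2 to 191, n = 3228). The difference of 41.9 had p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest they can give. In the lists of the single replicates, whose signals need not be on the same scale, the difference was 16.5 and 18.3. The share of summits in promoters fell with signal, from 50.5% of the strongest 1284 peaks to 40.1%, 31.7% and 26.2% in successive sets of 1283 weaker peaks.

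**Figure D2:**
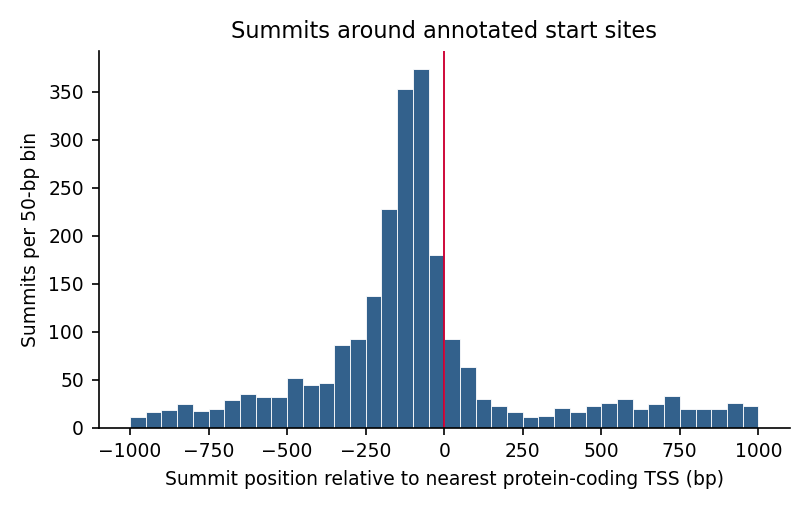
Number of summits by signed distance from the nearest protein-coding TSS in bp, in bins of 50 bp, with negative values upstream and a red line at the TSS. Summits pile up just upstream of the TSS, with a median of -111 bp among the 1905 within 500 bp.

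The third comparison concerned the genes of the sex determination pathway, the process in which sisA is known to act. Of 19 genes fixed beforehand 5 had a summit within 1000 bp of a TSS, against 2935 of 13926 other protein-coding genes (26.3% against 21.1%; odds ratio 1.34, 95% interval 0.532 to 3.79; Fisher's exact test, two-sided, adjusted p = 0.818). Sxl was among them, with a summit at X 7096685, in the gene and 381 bp downstream of the nearest annotated TSS, in a peak from 7096515 to 7096854 with a signal of 123 (73.7 in replicate 1 and 56.9 in replicate 2). The reference sequence there, at X from 7096665 to 7096705, was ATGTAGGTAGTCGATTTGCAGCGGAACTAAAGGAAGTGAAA. A pair of further peaks lay in Sxl introns, at 7094931 to 7095270 (signal 130) and 7095644 to 7095814 (signal 253), and another lay in an intron of the neighbouring CG4615, at 7101573 to 7101912 (signal 219). The strongest of the 4 was at 253, above the median of 128 for the list. The peak from 7096515 to 7096854, with its signal of 123, was below that median. Sxl has 4 annotated TSSs, at 7092883, 7097066, 7097768 and 7098053. Only the TSS at 7097066 had a summit within 1000 bp, so the call of Sxl as occupied rests on it alone.

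The other occupied genes were gro, a corepressor gene (103 bp, signal 161), dsx, which directs sexual differentiation (234 bp, 99.8), and fl(2)d and vir, both needed for Sxl-dependent splicing (177 bp, 306, and 280 bp, 168). The nearest summit was farther away for the X-linked signal genes, at 4086 bp for sisA itself, 13986 bp for upd1, 33827 bp for run and 97926 bp for sc. It lay at 1602 bp for da, 5111 bp for dpn, 3684 bp for emc, 2325 bp for her, 2881 bp for tra, 1168 bp for tra2, 1869 bp for fru, 37247 bp for ix, 13527 bp for snf and 6338 bp for msl-2. Over all 13945 protein-coding genes the median distance to the nearest summit was 7026 bp (interquartile range 1678 to 17701). With a single TSS per gene 3 of the 19 genes were occupied, and Sxl and dsx were no longer among them. The odds ratio of the list then turned to 0.790 (Fisher's exact test, adjusted p = 1).

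**Figure D3:**
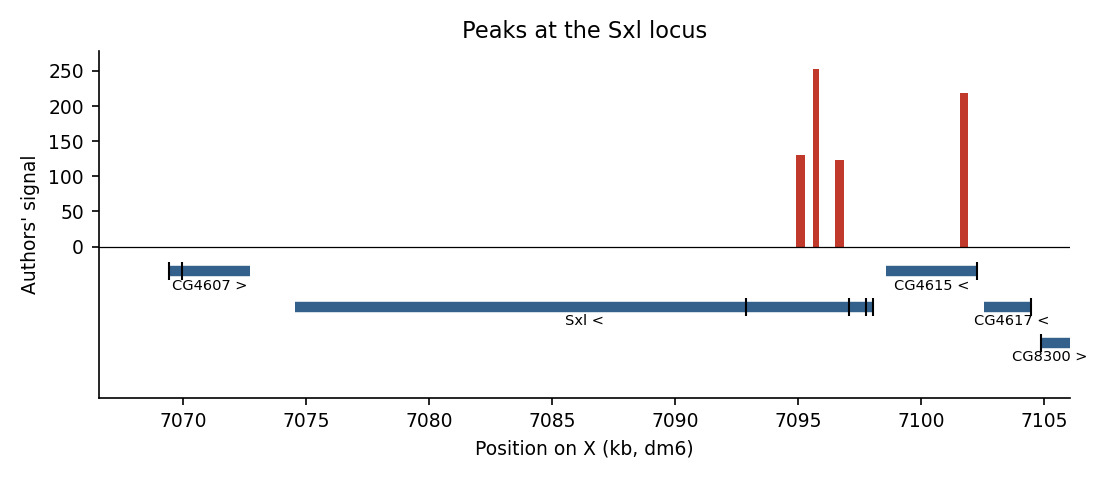
Map of the Sxl locus on X in dm6 from 7066550 to 7106053, with genes as blue bars, annotated TSSs as black ticks and the peaks of the conservative list as red bars whose height is the authors' signal. Of 4 peaks, 3 lie in Sxl and 1 in CG4615.

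The fourth comparison asked whether genes of the X chromosome were occupied more often than autosomal genes. A summit lay within 1000 bp of a TSS for 490 of 2196 X genes (22.3%) and for 2449 of 11669 genes on 2L, 2R, 3L and 3R (20.99%), an odds ratio of 1.08 (95% interval 0.969 to 1.21; Fisher's exact test, two-sided, p = 0.163). Summits numbered 44.6 per Mb on X, 39.6 on 2L, 35.9 on 2R, 37.1 on 3L and 37.4 on 3R. Chromosome 4 had a single peak, 170 bp from a TSS of the plexin gene PlexA, at 4 from 1027171 to 1027393 (signal 503), or 0.742 per Mb. In blocks of 1 Mb, an alternative chosen after seeing the data, X had 45.5 ± 19.4 summits (SD, n = 23) and the autosomal arms 37.8 ± 20.2 (SD, n = 108; permutation test, two-sided, p = 0.0954). Fisher's exact test treats neighbouring genes as independent, although they can share a summit, and randomly placed peaks gave a median odds ratio of 1.08 as well. The odds ratio fell below 1 among the stronger peaks (0.964) and in the list of replicate 1 alone (0.999). The sex of the embryos is not stated, so the copy number of X relative to the autosomes is unknown and was not corrected for. A further 65 peaks on unplaced X contigs took no part. An odds ratio near 1 therefore cannot tell whether the protein favours the X.

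The fifth comparison asked which groups of genes were occupied. In all, 2940 of 13945 protein-coding genes (21.1%) had a summit within 1000 bp of a TSS. Of 22 lists of genes, 1 was occupied more often than other genes and 5 less often at an adjusted p under 0.05. Genes of the cytoplasmic ribosome were occupied in 45 of 86 cases (52.3% against 20.9%; odds ratio 4.16, 95% interval 2.72 to 6.34; Fisher's exact test, two-sided, adjusted p = 1.14e-09). Their strongest peaks lay just upstream of RpL32 (signal 657), RpL34b (577), RpS27 (533) and RpL23A (512). These 4 genes encode structural proteins of the ribosome, and their summits were 29 to 176 bp from the TSS. The odds ratio was 2.44 among the stronger peaks and 2.71 over gene bodies (Fisher's exact test, adjusted p = 0.00206 and 2.76e-05). Control libraries were not used here, so binding of the fusion protein at these and other genes could not be told apart from background.

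Less often occupied were the chemosensory receptors of the odorant, gustatory and ionotropic families, with 6 of 179 (odds ratio 0.128; Fisher's exact test, adjusted p = 9.13e-11), and the cuticle proteins, with 4 of 108 (0.143; adjusted p = 1.92e-06). Or88a (signal 266), Or9a (110), Gr32a (103) and Ir60e (89.1) had the strongest receptor peaks, each in a promoter of some protein-coding gene, and Cpr73D (163), Cpr65Ay (130), Cpr65Ea (93.8) and Cpr92A (62.9) were the occupied cuticle genes. The receptor odds ratio was 0.0581 in replicate 2 alone, 0.0647 in replicate 1 alone, 0.0347 among the stronger peaks, 0.0776 within 500 bp and 0.210 within 2000 bp. For cuticle genes it was 0 within 500 bp and 0.215 within 2000 bp. None of 111 replication-dependent histone genes had a summit (adjusted p = 9.13e-11, Fisher's exact test). These genes are clustered, so that they are not independent, and rotating the lists along the gene order, a test added after seeing the data, gave an adjusted permutation p of 0.0177. The same permutation gave adjusted p = 0.00105 for ribosomal protein, receptor and cuticle genes and 0.00303 for tRNA genes. The copies of the histone gene repeat are near identical, and how reads that match several copies were treated is not given in the sources used here. Genes for tRNAs were occupied in 26 of 290 cases against 18.8% of other genes (odds ratio 0.425; Fisher's exact test, adjusted p = 2.67e-05), led by tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8, which share a peak of signal 541, and by tRNA:Val-TAC-1-1 (277) and tRNA:Phe-GAA-1-2 (198). Their odds ratio was 0.201 within 500 bp and 0.672 within 2000 bp. Genes for snoRNAs were occupied in 34 of 269 cases (odds ratio 0.628; Fisher's exact test, adjusted p = 0.0337), led by scaRNA:MeU5-C46 (472), the neighbours snoRNA:Psi18S-1295 and snoRNA:Psi28S-2562, which share a peak of signal 424, and snoRNA:Irbp-a (396). The summits named here for tRNA and snoRNA genes each lay in a promoter of some protein-coding gene, so they need not mark binding at the RNA genes themselves. The snoRNA call did not hold when lists were rotated (permutation test, adjusted p = 0.134). In exact tests it was also lost with a single TSS per gene (adjusted p = 0.171), in either replicate alone (0.358 and 0.144), in the longer list (0.0842), among the stronger peaks (0.277) and over gene bodies (0.740). Within 500 bp its odds ratio was 0.172, and within 2000 bp it turned to 1.28.

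Genes of bZIP factors, the family of sisA itself, were occupied in 9 of 20 cases (odds ratio 3.07, 95% interval 1.31 to 7.32), which missed the threshold (Fisher's exact test, adjusted p = 0.0717). Atf3 (signal 1006), REPTOR (683), the clock gene vri (289) and Irbp18 (285) had the strongest peaks. The list passed the threshold in replicate 2 alone (odds ratio 5.24; exact test, adjusted p = 0.00161), in replicate 1 alone (3.16; 0.0442), among the stronger peaks (5.14; 0.00256) and within 2000 bp (3.32; 0.0301). With a single TSS per gene the odds ratio was 1.41 (exact test, adjusted p = 0.710).

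None of 16 gap and pair-rule genes, which lay down the segments of the early embryo, had a summit within 1000 bp (Fisher's exact test, adjusted p = 0.0888), and their nearest summits were 4319 to 141021 bp away. The list passed the threshold within 2000 bp (exact test, adjusted p = 0.0301) and over gene bodies (0.0168), with an odds ratio of 0 in both. No summit was near any of 8 early zygotic cellularisation genes (Fisher's exact test, adjusted p = 0.434), 12 chorion and yolk protein genes (0.183) or 12 hemocyte and fat body genes (0.183). For the cellularisation genes this did not hold in the lists of replicate 2 alone (odds ratio 0.746) and replicate 1 alone (0.551), within 2000 bp (0.905) or over gene bodies (0.819). Within 2000 bp the odds ratio was 0.247 for chorion and yolk protein genes and 0.542 for hemocyte and fat body genes, the latter at 0.819 over gene bodies. The remaining lists also missed the threshold, with adjusted p of 0.476 or more in the same exact test.

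Among developmental regulators in those lists, 4 of 21 dorsal-ventral patterning genes were occupied, ush (signal 259), brk (223), Doc1 (92.5) and rho (74.7), all with summits 578 to 988 bp from the TSS. The odds ratio of that list was 0.881, and within 500 bp none of the 21 was occupied (exact test, adjusted p = 0.122). Segment polarity and Hox genes had 2 of 14, the Hox genes Dfd (88.0) and Antp (60.7), with an odds ratio of 0.624 that became 0 in replicate 2 alone and 0.296 in replicate 1 alone, and turned to 1.09 within 2000 bp and to 3.28 over gene bodies (exact test, adjusted p = 1 and 0.0741). Mesoderm and muscle genes had 3 of 12, tin (282), stumps (254) and the FGF receptor gene htl (131), and this list passed the threshold over gene bodies (odds ratio 7.38; exact test, adjusted p = 0.00464), while with a single TSS per gene 1 of 12 was occupied and the odds ratio turned from 1.25 to 0.383 (adjusted p = 0.678). Genes of endoderm and yolk nuclei had 3 of 8, bowl (561), peb (123) and fkh (61.3), at an odds ratio of 2.25. Neural genes had 2 of 14, elav, which marks neurons (904), and scrt (140), at an odds ratio of 0.624. The E(spl) complex, a set of Notch targets, had 4 of 11, E(spl)mdelta-HLH (278), E(spl)m3-HLH (271), E(spl)m7-HLH (125.2) and E(spl)m2-BFM (104), at an odds ratio of 2.14. Germ plasm and germ cell genes had 3 of 11, nanos (145), stwl (136) and vas (76.7). Dosage compensation genes had 1 of 8, msl-1 (98.4). Proteasome genes had 8 of 48, led by Rpn3 (283), Rpn5 (228), Rpn6 (216) and Prosbeta2 (173). Heat shock protein genes had 5 of 15, led by Hsp27 (1131), Hsp26 (201), Hsp22 (192) and Hsp60A (103).

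**Figure D4:**
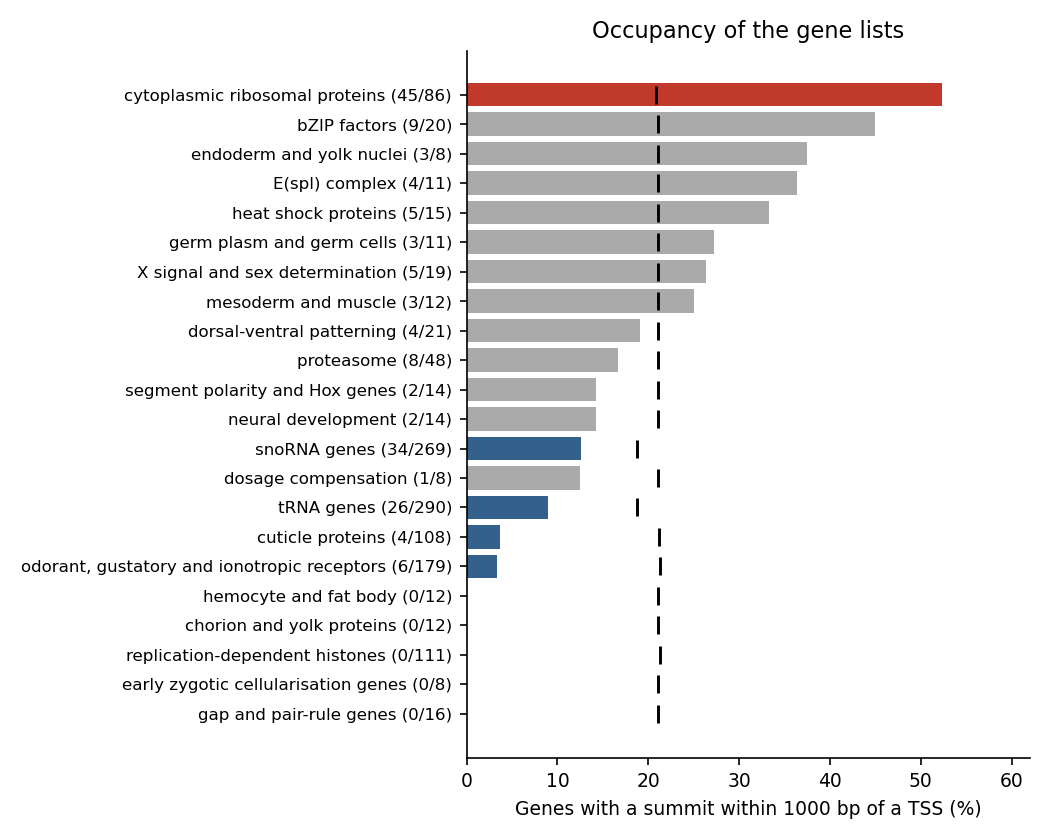
Share of the genes of each of 22 lists with a summit within 1000 bp of a TSS, in percent, beside the number occupied and the number of genes. Red and blue mark lists above and below other genes at an adjusted p under 0.05, grey marks the others, and the black tick gives the share among all other genes.

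The last comparison asked which short sequences marked the summits. Among 18 motifs, 4 were found within 100 bp of a summit more often than 500 bp away and 3 less often. Calls were common in this test: of all 2080 words of 6 bases, 528 were called higher and 996 lower. A call alone therefore does not set a motif apart from other words. The GAGA factor and E-box words were not compared with words of the same bases in another order. The TATA box word TATAAAA was present in 15.3% of summit windows and 7.55% of flanking windows (ratio 2.03; exact McNemar test, two-sided, adjusted p = 1.06e-35). The DRE TATCGATA, bound by the promoter factor DREF, was present in 2.36% against 0.468% (ratio 5.04; exact test, adjusted p = 3.07e-14), and motif 1, bound by M1BP, in 1.13% against 0.282% (3.48e-06). The PAR bZIP word TTAYRTAA was the 1 bZIP motif above its flanks, at 4.23% against 2.44% (1.74; exact test, adjusted p = 8.88e-07). All of its fixed bases are A or T, and summit windows were richer in these than the flanks (62.7% against 56.5%). It was not compared with words of the same bases in another order, so base composition was not separated from this excess. Against promoters without a summit, the ratio was 0.334 for DRE and 0.237 for motif 1 (Fisher's exact test, adjusted p = 9.44e-37 and 3.37e-35) and 0.996 for the TATA box. The PAR bZIP word was called higher there too, at a ratio of 1.78 (Fisher's exact test, adjusted p = 2.05e-09). Those promoter windows were centred on the TSS, while 37.1% of all summits lay in promoters, at a median of -111 bp from it. These ratios therefore compare unlike positions and do not show that occupied promoters lack or favour these motifs. Among the stronger peaks motif 1 no longer passed the threshold against the flanks (ratio 3.2; exact test, adjusted p = 0.0922).

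The GAGA factor word GAGAGAG was less frequent at summits, at 2.55% against 4.71% (ratio 0.541; exact McNemar test, adjusted p = 2.39e-08), as were its longer form of 10 bases (0.367; 5.86e-05) and the E-box CACGTG (0.736; 0.0381). In windows of 50 bp to each side the ratios were 0.207 for the GAGA word and 0.179 for its longer form. In windows of 200 bp the ratio was 1.03 for the GAGA word, and the calls of the longer form and the E-box were lost (exact test, adjusted p = 0.378 and 0.716). The E-box call was also lost in the longer list of the series (adjusted p = 0.0991, exact test). The other bZIP motifs did not pass the threshold, with ratios of 0.820 for AP-1, 0.714 for CRE, 0.870 for C/EBP and 0 for CrebA, which was at 0.667 in replicate 1 alone and 0.615 in windows of 200 bp. Neither did those of the early activator Zelda (0.845), GATA factors (1.18), bicoid (0.955) and caudal (0.995), the E-boxes CAGCTG (0.908) and CATATG (1.06), or the shuffled control (0.844). CAGCTG was called lower among the stronger peaks (0.802; exact test, adjusted p = 0.0158), in replicate 1 alone (0.794; 0.00999), in windows of 50 bp (0.731; 0.0136) and against promoters without a summit (0.698; 3.13e-12), and higher in windows of 200 bp (1.08; 0.0138). Besides the PAR bZIP word, CATATG (1.73; exact test, adjusted p = 6.97e-14) and caudal (1.20; 0.000233) were called higher against those promoters. Bicoid (0.857; exact test, adjusted p = 0.0335) and the shuffled control (0.473; 0.000575) were called lower against them. Bicoid was also called lower in windows of 200 bp (0.846; exact test, adjusted p = 0.0397), and GATA higher in replicate 1 alone (1.25; 0.0185). Of 2080 words of 6 bases, 528 were more frequent and 996 less frequent at summits than in the flanks, led by TTAAAA, in 47.0% of summit windows and 25.97% of flanks (exact McNemar test, adjusted p = 1.73e-101). Summit windows were 62.7% A and T, against 56.5% in the flanks and 58.9% over the arms.

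**Figure D5:**
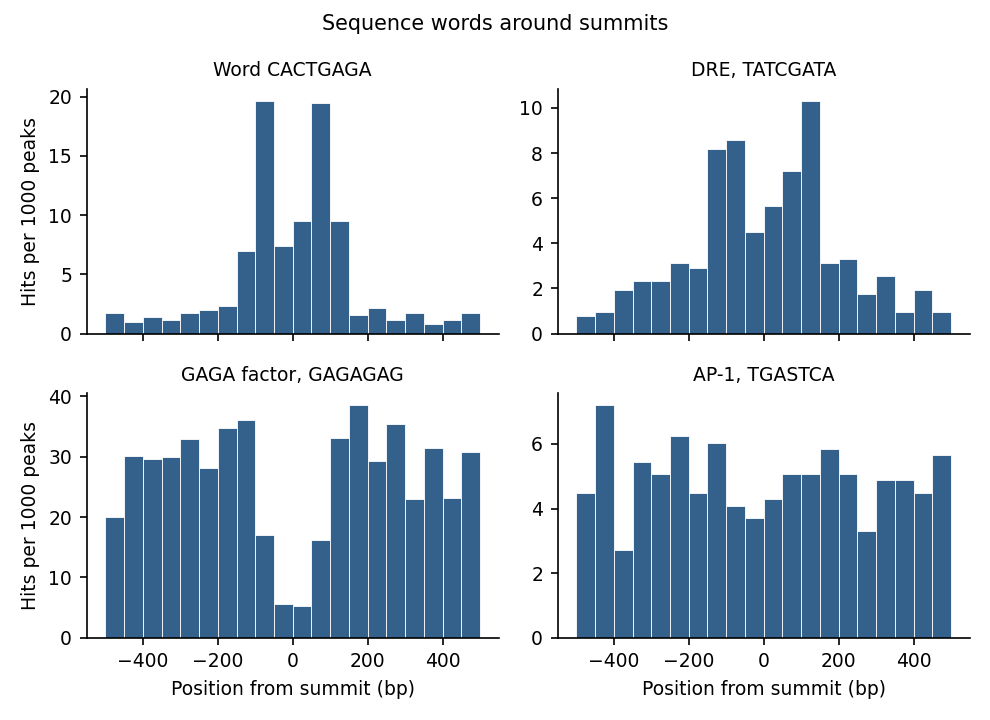
Hits per 1000 peaks in bins of 50 bp by distance from the summit in bp, for the words of DRE, GAGA factor and AP-1 and for CACTGAGA, a word of 8 bases chosen after seeing the data. DRE and CACTGAGA are more frequent near summits and GAGA factor less.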

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

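No test of this part was chosen after its result was seen. Peaks outside the chromosome arms take no part in the comparisons, and the conservative list held 69 of them, above the limit of 3 that a count of 0 allows. Nothing predicts a count of 0 there, so passing that limit says only that such peaks were listed. Of these, 65 lay on 37 unplaced contigs assigned to the X chromosome and 4 on the Y chromosome. The median signal on the unplaced X contigs was 95.4, against 128 on the arms. The ranked list held 3194 such peaks, 569 on unplaced X contigs, 970 on Y and 1655 on contigs of unknown origin.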

How the results depend on the processing

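Words of 8 bases, removal of peaks with a signal under 20, rotated gene lists and 1-Mb blocks were tests chosen only after the results were seen, and the other alternatives were planned. Of 220 alternatives for gene list odds ratios 195 kept direction and side of the threshold, as did 109 of 144 for motif ratios and 32 of 35 for location ratios. Many of these were for results that were not called. For results called in the main analysis, 52 of 60, 48 of 56 and 27 of 28 did so, while 1, 4 and 0 changed direction. For replicate agreement, 76.9% to 95.2% of replicate 2's peaks and 55.5% to 79.2% of replicate 1's were matched under other rules, and leaving out a replicate cannot be run there. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on the number of peaks was not tested. The cause was not tested for any change given here.

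With each replicate left out in turn, the list held 3485 to 4751 peaks, the promoter ratio was 3.44 to 3.62, the X odds ratio 0.999 to 1.00, called lists 6, called motifs 7 to 9, more frequent words of 6 bases 490 to 556, and the signal difference 16.5 to 18.3 on the scales of the single replicates. Odds ratios were 3.16 to 5.24 for bZIP factors, 0.745 to 1.01 for the proteasome and 0.694 to 0.734 for snoRNA genes. Further ranges with an end over 1.5 times away from the value of the full list were 0.0502 to 0.101 for coding sequence, 0.0581 to 0.0647 for receptors, 0 to 0.296 for segment polarity and Hox, 0.549 to 0.907 for dorsal-ventral, 0.551 to 0.746 for cellularisation, 1.29 to 1.74 for endoderm, 0.401 to 0.642 for neural and 1.16 to 2.20 for E(spl) genes, and 0 to 0.667 for the CrebA motif. Motif ratios were 0.971 to 1.03 for C/EBP, 0.794 to 0.844 for the E-box CAGCTG, 1.25 to 1.28 for GATA, 1.07 to 1.11 for caudal and 0.930 to 1.02 for the shuffled control.

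Among the stronger peaks the X odds ratio was 0.964, and list odds ratios were 0.895 for endoderm, 1.04 for neural, 5.14 for bZIP and 0.687 for snoRNA genes. The motif ratios there were 1.08 for C/EBP, 0.802 for CAGCTG, 3.2 for motif 1, 1.03 for bicoid and 1.11 for caudal, and the 5' UTR ratio was 0.586. In the longer list the odds ratio of snoRNA genes was 0.679 and the E-box CACGTG ratio 0.809. The intron ratio was 1.05 with promoters of 250 bp and 0.891 with 1000 bp. With a single TSS per gene the odds ratios were 0.790 for sex determination, 0.383 for mesoderm and 0.696 for snoRNA genes. In that setting they were 0.324 for segment polarity and Hox, 0.443 for dorsal-ventral, 1.41 for endoderm and 1.41 for bZIP genes. Rotation left the snoRNA odds ratio at 0.628 and ended its call (adjusted p = 0.134, permutation of gene order). Within 500 bp the odds ratio was 0.660 for endoderm and 0 for dorsal-ventral genes. Within 2000 bp it was 0 for gap and pair-rule, 1.09 for segment polarity and Hox, 3.32 for bZIP and 1.28 for snoRNA genes. Over gene bodies it was 0 for gap and pair-rule, 3.28 for segment polarity and Hox, 1.51 for dorsal-ventral, 7.38 for mesoderm, 1.36 for neural and 0.933 for snoRNA genes.

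In windows of 50 bp the ratios were 1.08 for C/EBP, 0.731 for CAGCTG, 1.07 for bicoid and 1.13 for caudal. In windows of 200 bp they were 1.03 for GAGA factor, 1.00 for C/EBP, 0.958 for CACGTG, 1.08 for CAGCTG, 0.846 for bicoid, 1.01 for caudal and 0.887 for the GA word of 10 bases. Against promoters without a summit 11 motifs were called, and the ratios were 1.15 for CRE, 1.06 for AP-1, 1.14 for C/EBP, 0.698 for CAGCTG, 1.73 for CATATG, 0.334 for DRE, 0.237 for motif 1, 0.917 for GATA, 0.857 for bicoid, 1.20 for caudal, 0.996 for the TATA box and 0.473 for the shuffled control. That background holds promoters only, while the summits include distal sites. Of words of 8 bases, of which there are more, 1807 were more and 1660 less frequent at summits, against 528 and 996 of 6 bases.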

Other observations

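All gene groups, words of 8 bases and divergent pairs described here, and the tests of filtering on chromosome 4, of base composition of summits, of annotated transposons and of the TATA box, DRE and motif 1 words, were chosen only after the results were seen. Among the strongest peaks were those at the mitochondrial ribosome genes mRpL41 and mRpL23, and 5 further groups were then tested. The peaks of rank 15 and 17, named above by their nearest TSS as CenG1A and Art3, also lay near such genes. Their summits were 387 bp from a TSS of mRpS23 and 136 bp from one of mRpS10. Mitochondrial ribosomal proteins were occupied in 24 of 73 cases (odds ratio 1.84; Fisher's exact test, adjusted p = 0.0681), Mediator subunits in 10 of 25 (2.50; 0.0681), vacuolar ATPase subunits in 12 of 33 (2.14; 0.0845), complex I subunits in 8 of 40 (0.936; 1) and translation initiation factors in 7 of 44 (0.707; 0.580). None of these 5 passed the threshold.

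A divergent TSS lay within 1000 bp for 1357 of 2193 genes with a summit within 500 bp of a single TSS per gene (61.9%) and for 3293 of 11752 others (28.0%), an odds ratio of 4.17 (Fisher's exact test, two-sided, p = 3.18e-197). A single summit between divergent genes marks both as occupied, which raises the odds ratio and makes this p too small. When 1552 summits were placed at randomly drawn genes, at the observed distances from the TSS, the median odds ratio over 200 draws was 1.87 (range 1.60 to 2.26). With each summit given to its nearest TSS alone the odds ratio was 2.04, against a median of 0.980 (0.824 to 1.16) for the placed summits. In the conservative list 100 peaks had a signal under 20, and 98 of them lay within 500 bp of a stronger peak, at a median distance of 203 bp.

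Chromosome 4 held 12 peaks in the ranked list and 1 in the conservative list. Repeat-rich sequence was argued against, since windows of other arms with a like share of soft-masked bases had 66.3 times as many ranked peaks per Mb (95% bootstrap interval 21.7 to 791). Filtering between the ranked and the thresholded list was argued against as well, since the other arms had 99.8 times as many ranked peaks per Mb (34.1 to 1111). Exclusion of the chromosome before ranking and a chromosome that differs in the strain were not tested. The design has 1 group, so no biological explanation was tested.

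The word of 8 bases with the smallest p at summits was CACTGAGA, in 268 summit windows and 30 flanking windows (exact McNemar test, adjusted p = 2.61e-45), with the consensus TGCACTGAGAGAAA around it. Base composition of promoters or of summits was argued against: over 1000 bp from every TSS the ratio was 12.3 (95% bootstrap interval 7.90 to 22.1), and on arms not used to pick the word, which was the same in both directions, at least 99.6% of words with the same bases in another order had a lower ratio. Copies of annotated transposons were argued against too, since 0% of 277 words at summits lay in one. Shared repeats remain a candidate explanation. Of the word's bases at summits 65.0% were soft-masked, against 16.0% of all bases in the flanks, a ratio of 4.06 (3.70 to 4.45). Words away from summits were 26.1% soft-masked, so the high share belonged to the copies at summits. Copies of a long repeat would share more sequence, however: over 10 bases from the word no base was common to more than 42.2% of copies. No biological explanation was tested for want of a second group.

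The summit lay downstream of CACTGAGA, read on the strand that carries it, in 384 of 428 words within 300 bp (89.7%; exact binomial test, two-sided, adjusted p = 3.02e-68), at a median of 73 bp. Of the other 3 words tested, TACACTGA had the summit downstream in 84.6% (median 77 bp), and TCAGTGCA and CAGTGCAC, which carry the core CACTG on the opposite strand, in 17.0% (median -71 bp) and 29.7% (median -64 bp). All of these words share CACTG, so their hits can be the same sites. Their results are therefore not independent of that for CACTGAGA. The strongest peaks with the word were near CG12769 (signal 1239), edl (1035), ImpL2 (955) and lncRNA:CR44149 (919). None of the 20 strongest peaks of the list had it, which are too few to tell a lack of the word. It was in 5.61% of the strongest 1284 summit windows, and in 5.30%, 5.77% and 4.21% of successive sets of 1283 weaker ones.

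For the TATA box word, only 20 words have the same bases in another order. Only a ratio above all of them could pass the level set for an excess. Of these words 90% had a lower ratio, short of that level, so base composition of summits remains a candidate explanation that the test could hardly exclude. For the DRE word that share was 100% of 591 words, with a ratio to the right-hand flank of 4.26 against at most 4.2, and for motif 1 it was 95.5% of 7559 words, also short of that level. No biological explanation was tested.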
